A study of Mus musculus with 5 samples.

How the data were processed

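Gene expression had been measured on Affymetrix mouse expression arrays, with 1 array for each of 5 groups of BALB/c splenic CD4 T cells. The groups, taken from the labels, were naive, control effector, Rap effector, TOFA effector and memory Th1 cells. The labels attach the same culture protocol to all 5 samples, while only the names of the effector samples describe cultured cells. Per the submitters' processing notes, the signals were made with GCOS and Affymetrix Expression Console, whose versions and algorithm are not given in the sources used here. The deposited values are in the unit intensity, a linear signal per probe set. Their mean after trimming 2% was 500.003 on every array, which is a scaling of each array to a target of 500. No probe set had the same signal on any pair of arrays.

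Array medians differed by 0.658 on the log2 scale, more than the 0.5 set as the limit, so the arrays were quantile normalized, and the values as deposited became an alternative. Values under the 40th percentile, a signal of 43.4, were raised to it as a floor, and genes at the floor in both arrays were not compared. After 64 control probe sets were set aside, 34945 of 45037 probe sets had 1 gene symbol in the platform's 2016 annotation, 932 had several and 9160 had none. The Entrez identifier matched for 34741 of them and 0 symbols were updated. The probe set with the highest mean log2 signal stood for each of 18193 genes, of which 14522 were above the floor in at least 1 array. A gene counted as higher or lower from a 2-fold difference.

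With 1 array per group, no test between groups was made. As the only internal measure of error, the spread between probe sets of the same gene was used to simulate how many genes pass 2-fold from this noise alone. The spread leaves out differences between arrays or cultures that all probe sets of a gene share. It can also hold true differences between probe sets, so the simulated counts are not those expected between replicate arrays. The SD of this spread on the log2 scale was 0.59 for control effector against naive, 0.34 for TOFA and 0.35 for Rap against control effector. It was 0.61 and 0.48 for memory against control effector and naive, and 0.32 for TOFA against Rap. The SD was larger in comparisons with more genes past 2-fold. Among 2-fold genes with other probe sets, these went the same way for 89.9%, 80.7%, 82.9%, 91.5%, 91.7% and 88.1%, and were also past 2-fold for 51.7%, 27.2%, 36.4%, 55.2%, 50.8% and 32.6%, in the same order. Spearman's rho between arrays lay between 0.854 and 0.932.

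The 36 gene lists, the 6 comparisons, the 6 correlations across genes, the rule for named genes and the alternatives were fixed before the data were examined, apart from the additions named as chosen later. The lists held 706 entries, of which 644 matched a gene on the array. Each list's median difference was set against 10000 random lists matched on mean expression in 20 bins, and was called higher or lower outside percentiles 2.5 and 97.5. Genes were named by a rule with 3 parts. The first was 23 fixed genes, where measured, some of which are not reported here. The next was the 8 genes furthest higher and the 8 furthest lower in each comparison, past 2-fold, with the higher array at or above the 60th percentile (signal 150.4) and all probe sets of the gene above the floor going the same way, skipping predicted genes. The last was up to 4 members of each list with the largest differences. Correlations that share the control array were compared with simulated groups without any difference. All simulated groups were given noise of equal spread, which fixes the simulated r in advance. That noise, from TOFA or Rap against control and drawn without regard to signal level, likewise fixes the simulated covariance.

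The procedure was tested on simulated data. The changed genes were drawn from those at or above the 60th percentile of the control array, and noise was drawn without regard to signal level. In simulated TOFA and control arrays, 10%, 56%, 92% and 98% of genes with true folds of 1.5, 2, 3 and 4 were counted, and 0.956% of unchanged genes. For Rap the values were 8%, 48%, 98% and 100%, with 1.07% of unchanged genes. For memory against naive they were 14%, 46%, 88% and 98%, with 4.43%. For TOFA against control, the probe set noise matched on signal level gave a mean of 267 of 12850 genes, a larger share than 0.956%. The shares of changed genes counted do not cover genes near the floor. Of 100 random lists of 20 genes, 4, 3 and 4 were called, and all 100 lists shifted by 0.5 were called. These lists came from the same simulated genes as their reference lists. The check therefore does not show how often lists of genes that vary together are called.

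The alternatives were the values as deposited, floors at the 20th and 60th percentiles, the mean of all probe sets of a gene, leaving out probe sets that can match several transcripts (_x_at and _s_at), an added constant of 43.4 in place of the floor, and thresholds of 1.5-fold and 3-fold for counts. A restriction to the 10052 genes above the floor in the 4 arrays other than memory was added after the memory array had been seen. Probe sets with no gene or several genes were not used in the gene comparisons. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.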

Results

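Gene expression was measured on Affymetrix mouse arrays in CD4 T cells from the spleen of BALB/c mice, with 1 array in each of 5 groups. The groups were naive cells, control effector cells, effector cells labelled TOFA, effector cells labelled Rap, and memory Th1 cells. Effector cells had been stimulated for 5 days with 15 ng/ml IL-2 and 10 ng/ml IL-12, cytokines that drive T cell growth and the interferon-gamma producing Th1 fate. TOFA is an inhibitor of acetyl-CoA carboxylase, which makes the malonyl-CoA needed for fatty acid synthesis and is encoded by Acaca (the Acc1 of the study's title) and Acacb. The label Rap is not expanded in the labels. Each array listed 45101 probe sets, and the median signal as deposited was 74.2 in naive, 68.7 in control effector, 66.9 in Rap effector, 63.1 in TOFA effector and 99.5 in memory cells. The ratio of the 3' to the 5' control probe set, a sign of RNA quality, lay between 0.832 and 0.918 for Gapdh and between 1.26 and 1.45 for beta-actin.

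No group had a replicate, so no p-value and no SE or SD between replicates can be given, and the number of arrays limits the precision of every value. "Higher" and "lower" describe these arrays, with genes counted from a 2-fold difference. Counts from probe set noise leave out differences between single cultures, so an excess over them is not a count of group differences. A gene at the floor in 1 array has a lower bound, written as "at least". Gene lists are called higher or lower where the list's median lay outside the central 95% of 10000 random lists matched on expression, and the percentile given with a median is its place among those random lists. Some genes are members of several lists. List medians are on the log2 scale.

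The comparison of control effector with naive cells asked how expression differed after Th1 culture. Genes of cell division, glucose use, lipid synthesis and the Th1 program were higher in the control effector array. Gzmb, which encodes the cytotoxic protease granzyme B, was 107-fold higher (signal 28439.8 against 266). Ifng, the gene of interferon-gamma, was at least 94.7-fold higher, and Tbx21, which encodes the Th1 transcription factor T-bet, was 16.8-fold higher. The naive cell genes Klf2, a transcription factor of T cell quiescence, and Ccr7, the lymph node homing receptor, were 15.2-fold and 3.71-fold lower. In all, 3571 of 13070 genes compared were at least 2-fold apart, 2078 higher and 1493 lower, and probe set noise alone gave a mean of 1086. With the values as deposited the split was 1876 higher and 1810 lower.

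All 27 measured mitosis genes were at least 2-fold higher in control effector cells, with a list median of 4.80, percentile 100. Aurkb, a kinase of chromosome segregation, was 61.6-fold higher and Mki67, a marker of cycling cells, was 26.4-fold higher. All 32 DNA replication genes were also past 2-fold, with a median of 2.84, percentile 100, including Rrm2, a subunit of the enzyme that makes deoxynucleotides (29.8-fold). Of 19 glycolysis genes, 17 were at least 2-fold higher (median 2.44, percentile 100), among them the hexokinase gene Hk2 (58.9-fold) and the aldolase gene Aldoc (94.3-fold). The hypoxia response list had 18 of 20 members at least 2-fold higher (median 3.35, percentile 100), led by Egln3, an oxygen sensor that marks HIF for degradation (118-fold). The STAT5 and cytokine response list had 13 of 16 members at least 2-fold higher (median 1.97, percentile 100), including Il2ra, the high-affinity IL-2 receptor chain (11.2-fold), and Socs2 (33.1-fold). Among the single genes with the largest differences were Emilin2 (167-fold higher), the transglutaminase gene Tgm2 (166-fold), Enah (at least 133-fold) and the transcription factor gene Nfil3 (at least 132-fold). The 4 other probe sets of Enah had a median of 3.23 on the log2 scale, against 7.05 on its brightest.

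Lipid synthesis genes were higher in control effector than in naive cells. Of 20 cholesterol synthesis genes, 19 were at least 2-fold higher (median 2.39, percentile 100), including Fdps, which makes farnesyl diphosphate (14.8-fold). Of 26 fatty acid synthesis genes, 16 were at least 2-fold higher (median 1.33, percentile 100). The desaturase gene Scd2 was 17.8-fold higher (signal 33506 against 1878), Scd1 was 4.96-fold higher, and Fasn, which encodes fatty acid synthase, was 3.12-fold higher. Acaca was 2.56-fold higher on its brightest probe set, while its other probe set differed by -0.64 on the log2 scale. The amino acid supply and ATF4 target list had 18 of 33 members at least 2-fold higher (median 1.02, percentile 100), including Asns, asparagine synthetase (16.6-fold). The lipid uptake list (4 of 6 members past 2-fold, percentile 99.8) and oxidative phosphorylation (median 0.40, 4 of 34) were higher as well. The fatty acid oxidation list lay inside the random range (median 0.40), and its rate-limiting transferase gene Cpt1a had signals of 1029 against 1812.

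Of 29 Th1 effector genes, 15 were at least 2-fold higher and 3 lower in control effector cells (median 1.05, percentile 100). Lta, which encodes lymphotoxin alpha, was 26.3-fold higher. The T cell memory list went both ways, with 7 members higher and 6 lower (median 0.61). The Th2 list had a median of 1.80 over 5 members, among them Il24 (13.8-fold higher) and Gata3, the Th2 transcription factor, which was 3.43-fold lower. The Th17, regulatory T cell, follicular helper and inhibitory receptor lists lay inside the random range, with medians of 0.67, 0.40, 0.21 and 0.73. Inside it as well were ribosome biogenesis and MYC targets (0.23), cytosolic ribosomal proteins (-0.01), the TCA cycle (0.27), apoptosis regulators (-0.16) and autophagy and lysosome (-0.15).

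Genes of the resting state were lower in control effector cells. The naive and central memory list had 16 of 22 members at least 2-fold lower (median -1.82, percentile 0), including Il6ra (21.0-fold) and Dapl1 (19.9-fold), and the FOXO1 and quiescence list had 17 of 22 (median -1.52, percentile 0). The interferon stimulated list had 12 of 24 members at least 2-fold lower (median -1.01, percentile 0), with Rtp4 32.8-fold lower. The TCR immediate early list had 10 of 20 members lower and 4 higher (median -0.92, percentile 0), with Egr1 50.5-fold lower and Ier3 at least 149.7-fold higher. The adhesion and trafficking list (median -0.52) and T cell identity list (median -0.93) were lower too. Markers of other spleen cells went the same way as all of these lower lists. B cell markers had a median of -2.49 (14 of 15 at least 2-fold lower), with Ighm, the immunoglobulin mu heavy chain, at a signal of 1352 against 27391, and myeloid markers a median of -1.56, with S100a8, a neutrophil calcium-binding protein, at 20.3 against 2917. Jchain, the joining chain of secreted antibodies, was at least 163-fold lower. The adhesion, Th2, lipid uptake and T cell memory lists moved inside the random range under at least 1 alternative, and Acaca was under 2-fold as a mean over its probe sets.

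**Figure D1:**
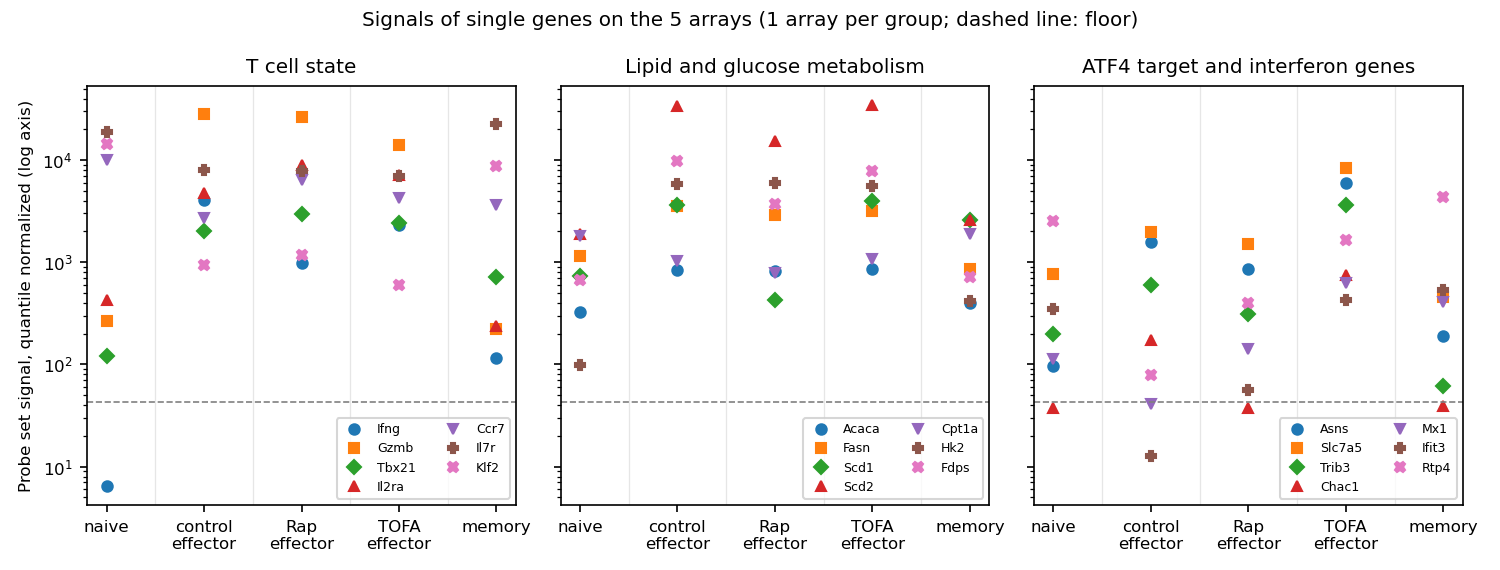
Probe set signals after quantile normalization (log axis) of 21 single genes on the 5 arrays, 1 array per group, with each point 1 gene and the dashed line the floor of 43.4. Gzmb stood at 266 in naive and 28439.8 in control effector cells, Scd1 was lowest in Rap effector cells at 425, and Trib3 reached 3672 in TOFA effector cells.

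The comparison of TOFA with control effector cells asked how effector cells given an acetyl-CoA carboxylase inhibitor differed from control effector cells. ATF4 target genes, many of which supply amino acids under nutrient or translation stress, and interferon stimulated genes were higher in the TOFA array. Cholesterol synthesis, hypoxia, glycolysis and mitosis genes were lower, nearly all by less than 2-fold. Rtp4, an interferon-induced gene, was 21.0-fold higher (signal 1641 against 78.1), though its other probe set differed by 0.30 on the log2 scale. Nupr1, a stress-response gene, was 17.1-fold higher, and Cth, the cystathionine gamma-lyase that makes cysteine, was 11.7-fold higher. In all, 594 of 12850 genes were at least 2-fold apart, 318 higher and 276 lower, and probe set noise alone gave a mean of 267.

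Of 33 amino acid supply and ATF4 target genes, 19 were at least 2-fold higher in TOFA cells, 32 lay above 0 and the median was 1.07, percentile 100. Atf5, a transcription factor of the same stress response, was 6.69-fold higher, the amino acid transporter genes Slc7a3 and Slc1a4 were 6.51-fold and 4.92-fold higher, and Trib3, a pseudokinase induced by ATF4, was 6.17-fold higher. Aldh1l2, a mitochondrial enzyme of folate metabolism outside the list, was 9.01-fold higher. The myeloid marker list went the same way, with a median of 0.49 over 10 members. Of these, only 1 was past 2-fold (Mpeg1, 155 against 7.47, the last under the floor). The ribosome biogenesis and MYC target list was higher by a median of 0.23, percentile 100 with 0 of 28 members past 2-fold, and Myc itself had signals of 4884 against 5076.

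Of 24 interferon stimulated genes, 13 were at least 2-fold higher in TOFA cells and all 24 lay above 0, with a median of 1.55, percentile 100. The antiviral GTPase genes Mx1 and Mx2 were at least 14.4-fold and at least 7.55-fold higher, Ifit3 was at least 9.78-fold higher, and Usp18, which restrains interferon receptor signalling, was 6.44-fold higher. The myeloid median of 0.49 moved with this list as well. The TCR immediate early list had a median of 0.27, percentile 99.7 with 4 of 20 members past 2-fold, led by Egr1 (11.1-fold), and the activation marker Cd69 was 2.65-fold higher.

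Among the Th1 effector genes, 2 were at least 2-fold higher and 3 lower in TOFA cells, with a median of -0.15, percentile 1.91. Gzmb was 2.03-fold lower, Prdm1, the transcription factor Blimp-1, was 2.81-fold lower, and the chemokine gene Ccl5 was 4.14-fold higher. Ifng had signals of 2301 against 4108 and Tbx21 of 2401 against 2036, both under 2-fold apart. The T cell memory list had a median of -0.18, percentile 0.890, with S100a4 3.71-fold lower and Id3 2.17-fold lower. The adhesion and trafficking list was lower with a median of -0.24 and 0 of 22 members past 2-fold. The naive and central memory list (median -0.05) and FOXO1 list (median 0.12) lay inside the random range, with Ccr7 at 4261 against 2712 and Il7r, the IL-7 receptor of resting and memory cells, at 7041 against 8065. Dendritic cell markers had a median of -0.33, percentile 1.03 beside these lower lists, with H2-Ab1, an MHC class II gene, 2.76-fold lower. Among the genes furthest lower were Fam183b (15.0-fold), the protease inhibitor gene Serpinb1a (8.50-fold), Serpinb5 (8.35-fold) and Endou (6.27-fold). The other probe set of Serpinb1a differed by -1.33 on the log2 scale, and the 3 others of Serpinb5 had a median of -1.49.

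Cholesterol synthesis, hypoxia, glycolysis and cell division lists were lower by small amounts in TOFA cells. Cholesterol synthesis had a median of -0.43, percentile 0 with 19 of 20 members below 0 and none past 2-fold, and Hmgcs1, an early enzyme of the pathway, stood at 11286 against 18454. The hypoxia list had a median of -0.47, percentile 0 with Selenbp1, a selenium-binding protein gene, 4.21-fold lower, and glycolysis a median of -0.19, percentile 0.510 with Aldoc 2.24-fold lower. Mitosis had a median of -0.35, percentile 0 with 27 of 27 members below 0, and DNA replication a median of -0.12, percentile 1.13, with no member of either past 2-fold. The dendritic marker median of -0.33 went the same way as these 5 lists. The fatty acid synthesis list lay inside the random range (median -0.06, 3 of 26 at least 2-fold lower). Acaca had signals of 857 against 836, Fasn of 3150.5 against 3582 and Scd1 of 3976 against 3622, while Acacb was 2.60-fold lower near the floor (51.6 against 134). Fatty acid oxidation, TCA cycle and oxidative phosphorylation lay inside the random range, with medians of 0.02, -0.09 and -0.05. Also inside it were STAT5 and cytokine response (-0.02), T cell identity (-0.11), regulatory T cell (0.07), apoptosis regulators (0.13) and B cell markers (0.12).

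With the values as deposited, the split between higher and lower genes turned from 318 and 276 to 275 and 386. The T cell memory, Th1, DNA replication, myeloid and dendritic lists moved inside the random range under at least 1 alternative, and Acacb and Gzmb moved under 2-fold.

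**Figure D2:**
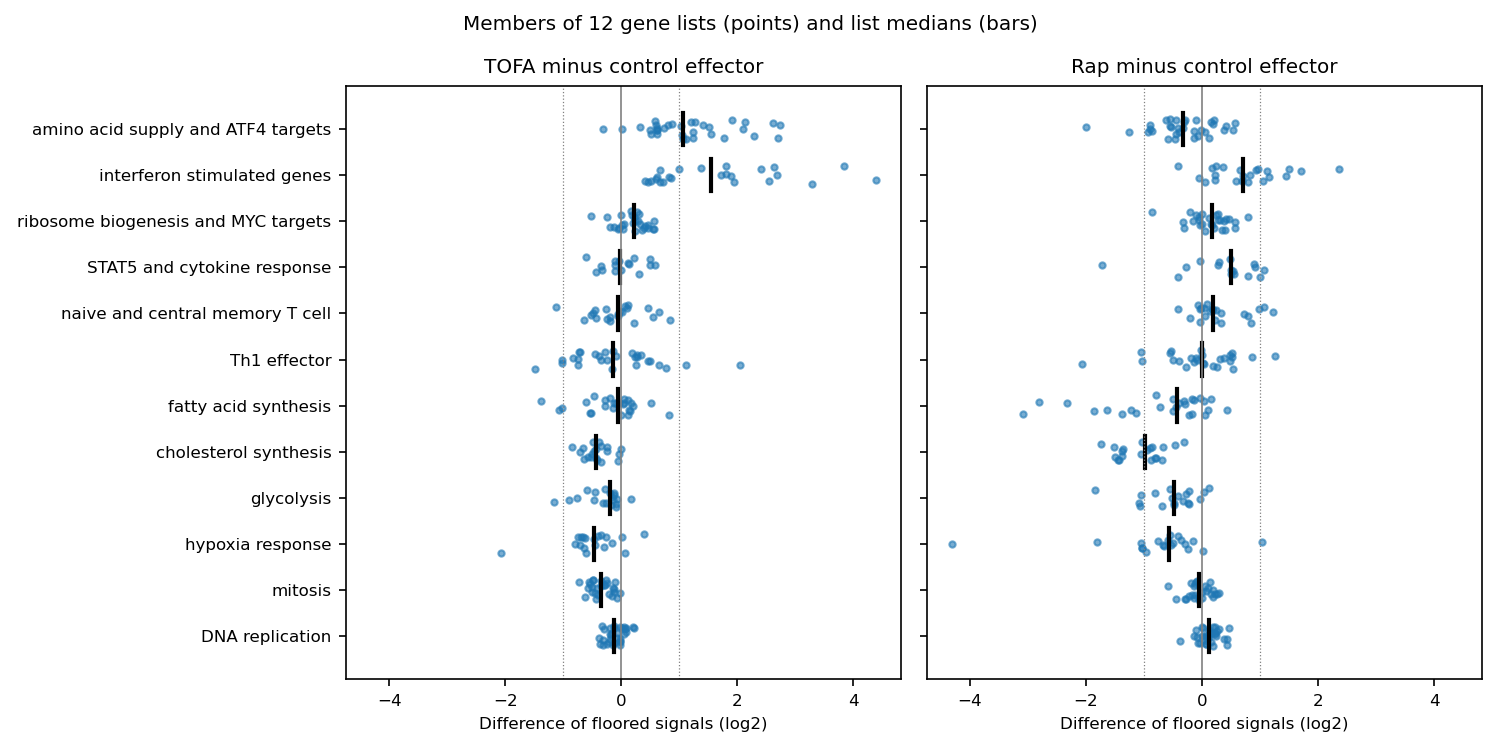
Difference in log2 signal between TOFA and control effector cells (left) and Rap and control effector cells (right) for the members of 12 gene lists, with each point 1 gene, bars at list medians and dotted lines at 2-fold. The ATF4 target median was 1.07 for TOFA and -0.32 for Rap, and the cholesterol synthesis median was -0.43 for TOFA and -0.99 for Rap.

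The Rap effector cells were compared with the same control array. By list medians, genes of cholesterol and fatty acid synthesis, glycolysis and the hypoxia response were lower in Rap cells. Those of the STAT5 and cytokine response and interferon stimulated lists were higher. Apart from cholesterol synthesis, most members of each of these lists were under 2-fold. Scd1, which makes monounsaturated fatty acids, was 8.52-fold lower (signal 425 against 3622), and Selenbp1 was 19.8-fold lower. Ifng was 4.19-fold lower (signal 980.1 against 4108), while Gzmb stood at 26476 against 28439.8. In all, 737 of 12851 genes were at least 2-fold apart, 234 higher and 503 lower, and probe set noise alone gave a mean of 281.

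All 20 measured cholesterol synthesis genes lay below 0 in Rap cells and 10 were at least 2-fold lower (median -0.99, percentile 0). Lss, which closes the sterol ring, was 3.34-fold lower and Dhcr7, a late enzyme of the pathway, was 2.81-fold lower. Of 26 fatty acid synthesis genes, 8 were at least 2-fold lower (median -0.42, percentile 0), including Me1, a source of NADPH (6.98-fold), Acss2, which makes acetyl-CoA from acetate (5.02-fold), Fads2 (3.65-fold), Scd2 (2.19-fold) and Acacb (at least 3.09-fold). Acaca stood at 816 against 836 and Fasn at 2921 against 3582. Glycolysis had 4 of 19 members at least 2-fold lower (median -0.47, percentile 0), with Aldoc 3.58-fold lower and the glucose transporter gene Slc2a3 2.08-fold lower, while Hk2 stood at 5959 against 5834. The hypoxia list had 5 of 20 members lower and 1 higher (median -0.57, percentile 0), with Ero1a, an oxidase of protein folding, 3.49-fold lower.

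The amino acid supply and ATF4 target list was lower in Rap cells, with 2 of 33 members past 2-fold and a median of -0.32, percentile 0. Chac1, a glutathione-degrading enzyme induced by ATF4, was at least 3.98-fold lower, and Ddit4, an inhibitor of mTORC1, was 2.40-fold lower. Fatty acid oxidation (median -0.24, percentile 0.120), TCA cycle (-0.22, percentile 0.170), oxidative phosphorylation (-0.15, percentile 0.0900), lipid uptake (-0.35, percentile 2.40) and autophagy and lysosome (-0.14, percentile 2.24) were also lower. Of their members only Vldlr, a lipoprotein receptor gene of the lipid uptake list, was past 2-fold (2.74-fold lower).

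In the other direction, the STAT5 and cytokine response list was higher by a median of 0.50, percentile 100, with 2 of 16 members at least 2-fold higher and 1 lower. The cytokine gene Lif was 2.10-fold higher, the kinase gene Pim2 was 2.01-fold higher, Tnfrsf9 was 3.28-fold lower, and Il2ra stood at 8999 against 4765. Interferon stimulated genes were higher by a median of 0.72, percentile 100 with 7 of 23 past 2-fold, including Rtp4 (5.13-fold) and Mx1 (at least 3.29-fold). The naive and central memory list had a median of 0.19, percentile 99.4, with Ccr7 2.33-fold higher and Igfbp4 2.09-fold higher. The regulatory T cell list had a median of 0.34, percentile 99.9, with Nt5e, the ectoenzyme CD73, 3.76-fold higher and Entpd1, the ectoenzyme CD39, 2.57-fold lower. TCR immediate early genes (0.34, with Egr1 4.05-fold higher), ribosome biogenesis and MYC targets (0.17, with Myc at 8783 against 5076) and DNA replication (0.13) were higher by these medians. B cell markers moved with all of these higher lists, with a median of 0.43, percentile 99.3 over 13 members and Ms4a1, the gene of CD20, 2.19-fold higher at 431 against 197. Th1 effector (median 0.00), T cell memory (0.07) and mitosis (-0.05) lay inside the random range, as did myeloid markers (-0.09). Ccn3 (7.27-fold), Aff3 (5.04-fold) and Selp, the adhesion receptor P-selectin (3.91-fold), were among the single genes furthest higher. The fatty acid oxidation, lipid uptake, TCA cycle, autophagy and B cell lists moved inside the random range under at least 1 alternative. Under at least 1 alternative, Acacb, Chac1, Entpd1, Lif, Ms4a1, Mx1, Nt5e, Slc2a3 and Tnfrsf9 moved under 2-fold.

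The TOFA and Rap arrays were compared directly, a difference that does not use the control array. ATF4 target genes were higher in TOFA than in Rap cells, with 22 of 33 at least 2-fold higher and a median of 1.17, percentile 100. Chac1 was at least 17.4-fold and Trib3 11.7-fold higher. Outside the list, Cth was 29.0-fold and Gpt2, an alanine transaminase, 15.3-fold higher. Interferon stimulated genes were higher by a median of 0.78, percentile 100 with 9 of 24 past 2-fold, including Ifit1 (7.83-fold) and Usp18 (4.27-fold), and Ifi202b was 13.4-fold higher. All 20 cholesterol synthesis genes lay above 0 (median 0.65, percentile 100), and 6 of 26 fatty acid synthesis genes were at least 2-fold higher (median 0.20, percentile 99.6), with Scd1 9.35-fold and Fads2 3.95-fold higher. Fatty acid oxidation (0.29), hypoxia (0.30) and glycolysis (0.15) were higher by small medians. Myeloid markers had a median of 0.40 beside these higher lists, inside the random range.

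Lower in TOFA than in Rap cells were the naive and central memory (-0.46, percentile 0), T cell memory (-0.34, percentile 0), STAT5 and cytokine response (-0.36, percentile 0), mitosis (-0.27, percentile 0) and DNA replication (-0.25, percentile 0) lists. Eomes, a transcription factor of memory and cytotoxic T cells, was 3.16-fold lower, Id3 2.11-fold lower and Pim2 2.16-fold lower, while Ifng was 2.35-fold higher. The regulatory T cell (-0.28), adhesion (-0.30), inhibitory receptor (-0.27) and dendritic cell (-0.25) lists were lower as well, and B cell markers had a median of -0.30 beside them, inside the random range. In all, 593 of 12802 genes were at least 2-fold apart, 420 higher in TOFA and 173 lower, and probe set noise alone gave a mean of 193. The split was 397 and 265 with the values as deposited, and the adhesion, inhibitory receptor, dendritic cell and glycolysis lists moved inside the random range and Id3 under 2-fold under at least 1 alternative.

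Differences of TOFA and of Rap from the shared control array were set side by side. At least 2-fold higher in both were 80 genes and lower in both 157, among 12316 genes compared in both. Of these genes 289 were higher and 276 lower in TOFA, and 210 higher and 503 lower in Rap, and independent lists of these sizes would share 4.93 and 11.3 genes, and simulated unchanged groups against the shared control gave 11.2 and 15.4. Higher in TOFA and lower in Rap were 10 genes, where independent lists would share 11.8 and the simulation gave 0.03. These were Cth, Chac1, Gpt2, Ifi202b, Arfgef3, Cox6a2, Cldn12, Cd1d2, Gch1 and Ccrl2, and Frat2 was the 1 gene lower in TOFA and higher in Rap, all named after their values were seen. Across 13385 genes, which are not independent replicates, Pearson's r of both differences was 0.54 (Spearman's rho 0.51). Equal noise in all simulated groups fixes the simulated r near 0.50. The covariance was 0.126 against 0.0574 in the simulation. The simulations drew the probe set noise of TOFA against control without regard to signal level. They left out differences of the control culture that all probe sets of a gene share. With 1 control array the control could not be split. Part or all of the excess in shared genes and covariance may thus come from the shared control.

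**Figure D3:**
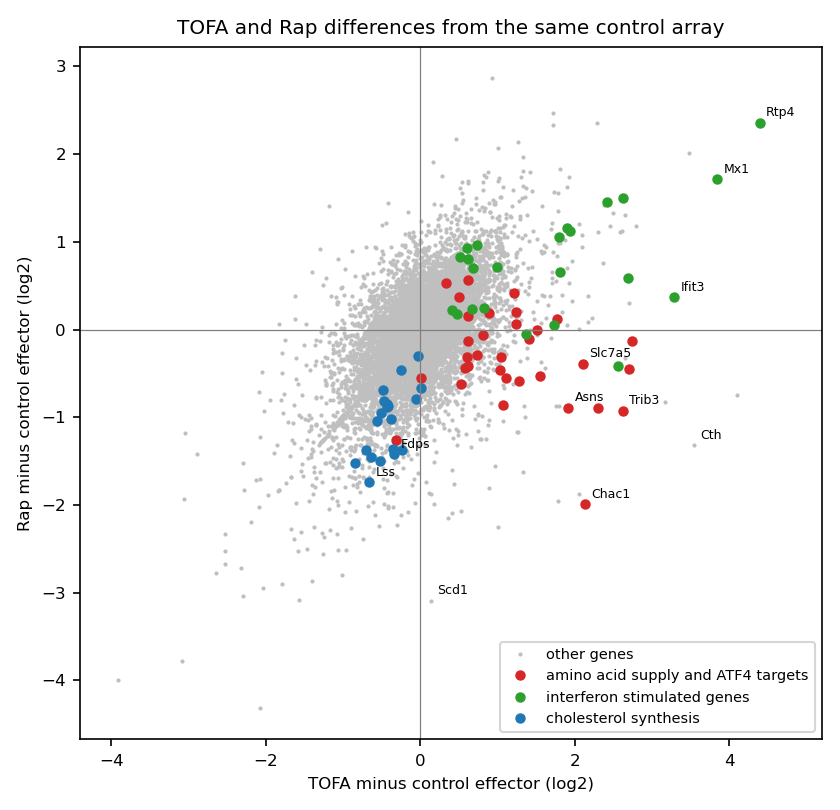
Difference in log2 signal of TOFA (horizontal axis) and Rap (vertical axis) from the same control effector array, with each point 1 gene and 3 gene lists in colour. ATF4 target genes such as Chac1 (at least 4.12 between TOFA and Rap) spread to the lower right, and cholesterol synthesis genes lay below 0 in Rap, where Lss was at -1.74.

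The memory array was compared with the control effector and naive arrays, to see which genes distinguish memory Th1 cells from each. The largest differences were in genes of macrophages and other non-T cells. Slc40a1, the iron exporter of splenic macrophages, was at least 813-fold higher in memory than in control effector cells (signal 35277 against 18.6) and 456-fold higher than in naive cells. C1qa, a complement component made by macrophages, was at least 382-fold higher than in either, and Spic, a transcription factor of splenic red pulp macrophages, was at least 353-fold higher. The myeloid list had a median of 7.13 against control effector and 5.91 against naive cells, with 21 of 22 members past 2-fold in both. B cell (4.26 and 1.32), dendritic cell (2.35 and 1.78), erythroid and platelet (3.32 and 2.48) and stromal (1.26 and 1.82) markers were higher in both comparisons. NK (0.73 and 0.36) and CD8 T cell markers (0.91 and 0.78) were higher against control effector cells and inside the random range against naive cells. T cell identity genes were inside the random range against control effector cells (median 0.09) and lower against naive cells (-0.49, percentile 0).

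**Figure D4:**
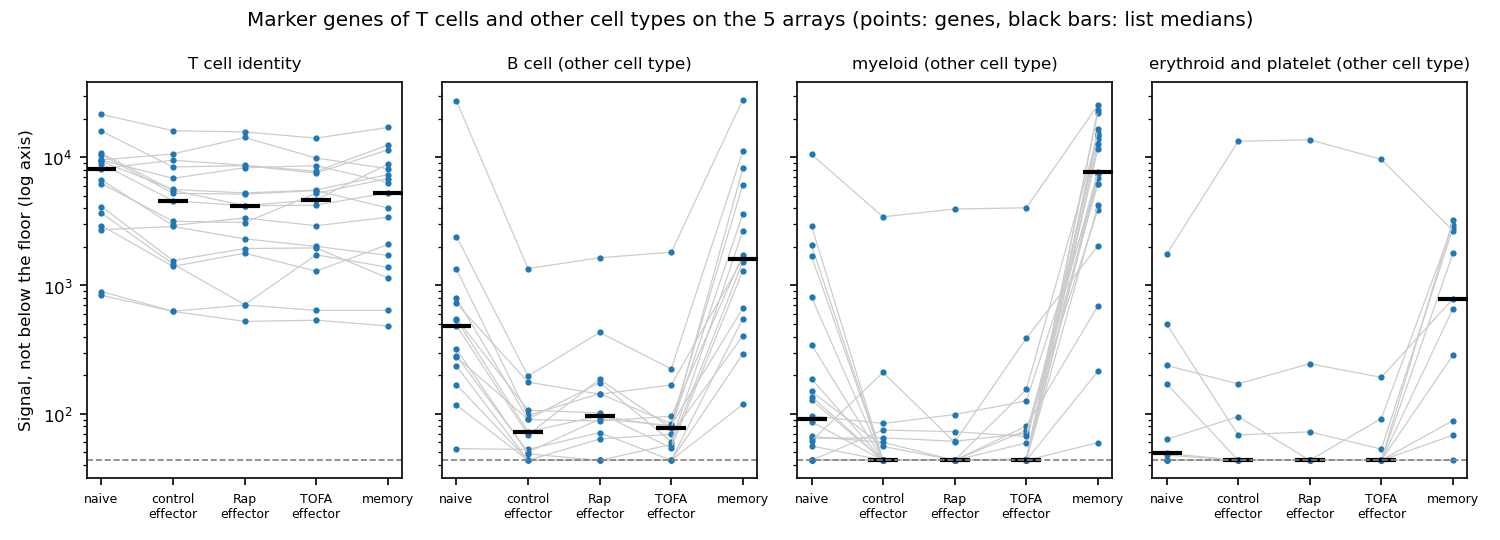
Signals (log axis, not drawn below the floor) of T cell identity genes and of B cell, myeloid, and erythroid and platelet marker genes on the 5 arrays, with points and grey lines for genes and black bars for list medians. Lyz1 stood at 22256 in memory, 2054 in naive and 9.55 in control effector cells, where the last is under the floor.

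Against control effector cells, growth and division genes were lower in memory cells. Mitosis had all 27 members at least 2-fold lower (median -4.85, percentile 0), DNA replication all 32 (median -2.85, percentile 0), and glycolysis 17 of 19 (median -2.27, percentile 0). The hypoxia list had 18 of 20 (median -2.94), cholesterol synthesis 19 of 20 (median -2.08), fatty acid synthesis 12 of 26 (median -0.88), and amino acid supply and ATF4 targets 18 of 33 (median -1.02). Scd2 was 13.0-fold lower, Fasn 4.18-fold lower and Acaca 2.10-fold lower, and Hk2 stood at 416 against 5834. Gzmb was 127-fold lower, Ifng 35.4-fold lower, and Lif at least 66.4-fold lower, and Il2ra stood at 239 against 4765, the STAT5 and cytokine response list having a median of -2.11. The other probe set of Lif differed by -2.24 on the log2 scale. Regulatory T cell (-1.65), follicular helper (-0.83), Th2 (-1.80) and oxidative phosphorylation (-0.34) lists were lower, while the Th1 effector list lay inside the random range (-0.12, 9 higher and 10 lower). Beside all of these lists, the myeloid median stood at 7.13 in the other direction.

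Higher in memory than in control effector cells were the T cell memory list (14 of 22 past 2-fold, median 1.40, percentile 100), the FOXO1 and quiescence list (11 of 22, median 0.93, percentile 100) and the naive and central memory list (7 of 22, median 0.49, percentile 99.3). Klf2 was 9.37-fold higher, Il7r 2.79-fold higher and the adhesion receptor gene Cd44, a marker of antigen-experienced T cells, 3.36-fold higher. The chemokine receptor genes Ccr2 and Cxcr6 were 16.7-fold and 10.6-fold higher. Adhesion and trafficking (17 of 26 members past 2-fold), autophagy and lysosome (0.55) and interferon stimulated genes (0.90) were higher too, with Ctsb, a lysosomal protease, 7.30-fold higher. The myeloid median of 7.13 and the B cell median of 4.26 moved with each of these lists. In all, 3805 of 13326 genes were at least 2-fold apart, 1932 higher and 1873 lower, against a mean of 1283 from probe set noise. With the values as deposited the median of all genes moved from -0.03 to 0.22 and the split to 2628 higher and 1382 lower. Over the 10052 genes above the floor in the other 4 arrays, a choice made after seeing the data, 1143 were higher and 1561 lower. The Th2, follicular helper, oxidative phosphorylation and CD8 lists moved inside the random range under at least 1 alternative, and Acaca moved under 2-fold.

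Against naive cells, the T cell memory list was higher in memory cells (11 of 22 past 2-fold, median 1.11, percentile 100), as was the Th1 effector list (14 of 30, median 0.92, percentile 100). Cxcr3, a chemokine receptor of Th1 cells, was 11.1-fold higher, Tbx21 5.85-fold higher, Cd44 5.58-fold higher and Maf 14.1-fold higher. The lipid uptake list had 5 of 8 members past 2-fold (median 2.26, percentile 99.9), with Lpl, lipoprotein lipase, at least 254-fold higher and Cd36, a fatty acid receptor, at least 50.4-fold higher. Fatty acid synthesis (0.36), fatty acid oxidation (0.23), TCA cycle (0.19), oxidative phosphorylation (0.07), autophagy and lysosome (0.47), adhesion (0.37) and Th17 (0.81) lists were higher by these medians. Scd1 was 3.57-fold higher on its brightest probe set, with 0.07 on the log2 scale on the other. The myeloid median of 5.91 and the B cell median of 1.32 moved with all of these higher lists.

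The naive and central memory list was lower in memory than in naive cells (10 of 22 past 2-fold, median -0.98, percentile 0), with Dapl1 15.6-fold lower and Ccr7 2.79-fold lower. FOXO1 and quiescence (-0.55), TCR immediate early (-0.55) and regulatory T cell genes (-0.62, with Ikzf2 8.08-fold lower) were lower, beside the myeloid median of 5.91 in the other direction. The T cell identity list went the same way as these lower lists, with a median of -0.49, percentile 0. A general fall of T cell transcripts in the memory array was not separated from these decreases. Mitosis (-0.10), DNA replication (-0.03), glycolysis (0.13), cholesterol synthesis (0.05) and ATF4 targets (-0.14) lay inside the random range. Acaca stood at 397 against 327 and Bcl2, an anti-apoptotic gene, at 6879 against 7736. In all, 2187 of 13082 genes were at least 2-fold apart, 1645 higher and 542 lower, against a mean of 716 from probe set noise. With the values as deposited the median of all genes moved from -0.05 to 0.06 and the split to 2056 and 302, and over the 10052 genes above the floor in the other 4 arrays it was 825 and 433. The Th17, TCA cycle and oxidative phosphorylation lists moved inside the random range under at least 1 alternative, and Scd1 moved under 2-fold.

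How the TOFA and Rap differences related to memory was described by 3 correlations across genes that share no array, of 6 computed. TOFA minus control had a Pearson's r of -0.02 with memory minus naive (Spearman's rho -0.03, 14255 genes), and Rap minus control had -0.10 (rho -0.11). TOFA minus Rap had 0.02 with memory minus control (rho 0.01, 14190 genes). The differences that share the control array had r of 0.28 for TOFA and 0.25 for Rap with memory minus control. Simulated unchanged groups gave 0.50 for each, and the covariances were 0.178 against 0.0573 and 0.168 against 0.0615. The simulated r of 0.50 follows from equal noise in all simulated groups. The probe set SD was 0.61 for memory and 0.34 for TOFA against control, so an r under 0.50 does not bear on resemblance to memory. The simulated covariances were set by the probe set noise of TOFA and of Rap against control. An excess over them does not bear on resemblance to memory either. Of single genes, Il7r stood at 7041 in TOFA, 7868 in Rap, 8065 in control effector, 22487 in memory and 18722 in naive cells. In the same order, Cd44 stood at 2739, 2591, 2692, 9058 and 1624. Ccr7, named above as a naive cell gene, stood at 4261, 6316, 2712, 3604 and 10056.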

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

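Of the tests in this part, the test on other probe sets for TOFA minus Rap was written before its result was seen, and those on other probe sets against control and on single cultures after it. The amino acid supply and ATF4 target list went opposite ways in the treated arrays, with a median of 1.07 for TOFA minus control and -0.317 for Rap minus control, a difference that could not be tested against replicates. Its members Chac1 and Trib3 were at least 17.4-fold and 11.7-fold higher in TOFA than in Rap cells. For the higher values in TOFA, single probe sets that misreport their gene are argued against by the 36 other probe sets of 23 list genes, with a median of 0.648 for TOFA minus control (33 above 0) and 0.769 for TOFA minus Rap (34 above 0). For the lower values in Rap this stays open, since 35 other probe sets had a median of -0.136 for Rap minus control, quartiles of -0.57 and 0.07, and 25 below 0. A difference between single cultures may also give this pattern, and with 1 array per group it stays open. A treatment effect of TOFA stays open as well, untested beyond these arrays.

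The DNA replication list also went opposite ways, with a median of -0.120 for TOFA minus control and 0.128 for Rap minus control. None of its 32 members passed 2-fold in either, and the difference between the groups was not tested against replicates. Under 2 alternatives, the mean over probe sets and the exclusion of _x_at and _s_at probe sets, the TOFA median moved inside the random range.

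Probe sets with no listed gene, which no comparison of the report used, also differed. Of 4810 compared between TOFA and control effector cells, 96 were at least 2-fold higher and 131 lower. Of 4884 compared between Rap and control effector cells, 165 were higher and 108 lower, a split opposite to that of the genes with a symbol, of which 234 were higher and 503 lower. The TOFA split was opposite as well, with 318 genes with a symbol higher and 276 lower. With the values as deposited the latter turned to 275 and 386. No count from probe set noise is given for the probe sets with no listed gene.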

How the results depend on the processing

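The restriction to 10052 genes was the only alternative chosen after the data were seen. Of 216 list medians, 114 lay outside the random range, 89 of them stayed outside it on the same side under each of the 6 alternatives for lists, and none was outside it on the other side. All 6 correlations moved by less than 0.1 under each alternative, and that of TOFA minus control with memory minus naive ranged from -0.0962 to -0.00352. Counts of 2-fold genes stayed within 1.5 times their value for all 6 comparisons with the values as deposited, the mean over probe sets, the exclusion of _x_at and _s_at probe sets and the added constant, though with the values as deposited the split between higher and lower turned for TOFA against control. For memory against control, with 1932 higher and 1873 lower, it turned to 1471 and 1611 with the mean over probe sets, 1848 and 1858 without _x_at and _s_at probe sets, 2743 and 2917 with the floor at the 20th percentile, 3215 and 3272 with 1.5-fold and 1143 and 1561 over the 10052 genes. The counts moved with the floor and threshold, which by construction admit more or fewer genes. With the floor at the 20th percentile they were 5690 for control effector against naive, 2448 for TOFA and 2686 for Rap against control, 4139 for memory against naive and 2458 for TOFA against Rap. At the 60th percentile they were 225, 286, 1322 and 239 for the last 4 of these. With 1.5-fold they were 6357, 2164, 2405, 4424 and 2047 in that order and 6487 for memory against control, and with 3-fold 1756, 141, 163, 1157, 128 and 2086. Over the 10052 genes, memory against naive gave 1258. Of 948 differences of named genes, 917 kept their direction and side of 2-fold with the values as deposited, 926 with the lower floor, 865 with the higher floor, 871 with the mean over probe sets, 903 with the added constant and 909 of 928 without _x_at and _s_at probe sets. Bik, an apoptosis gene and the only one to reverse, turned from -1.09 to 0.13 for TOFA against control without _x_at and _s_at probe sets. Its main probe set is an _x_at one, which this alternative leaves out, so another probe set gave the 0.13. Why these probe sets differ was not tested. Signals near the floor limit all of these counts.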

Other observations

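Of the tests in this part, those on the background of the memory array and on the brightest myeloid genes in the TOFA sample were written before their results were seen, and the others, as well as the use of deposited values for the background, after. The memory array held many transcripts of macrophages and other non-T cells, with a myeloid median of 5.91 for memory minus naive. Of the 5 brightest myeloid genes in memory cells, Vcam1 stood at 23380.1 against 4.37 in naive cells, C1qa at 16549.6 against 7.72 and Tyrobp at 15441 against 346. A higher background of the memory array as the whole cause is argued against by 45 genes of tissues foreign to the spleen, with a median of -0.0183 and quartiles of -1.02 and 1.65 for memory minus naive with the values as deposited. Their median was -0.418 after quantile normalization, which itself lowers an array with a raised low end, and 0 with the floor. RNA of other spleen cells in the memory sample is a candidate explanation, and no sorting step for this sample is described in the sources used here. B cell, dendritic cell, erythroid and platelet, and stromal markers were also higher than in naive cells (medians 1.32, 1.78, 2.48 and 1.82). NK and CD8 T cell markers lay inside the random range (0.36 and 0.78). Higher values in the memory array, such as those of Lpl and Cd36, were not separated from such RNA. Expression by the memory T cells themselves was not tested.

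Interferon stimulated genes were higher than control in both treated arrays. Over 25 members, the list's median level on the log2 scale was lowest in control effector cells, at 7.95. The level was 8.65 in Rap, 10.29 in TOFA, 9.77 in naive and 10.04 in memory cells. For TOFA, an unusual control array alone is argued against by the direct comparison with Rap, with a median of 0.780. RNA of myeloid cells like those of the memory array is argued against because only 1 of its 5 brightest myeloid genes was above the floor in TOFA cells, Ctss, which was above it in all 5 arrays. RNA of other myeloid cells in the TOFA sample stays open, since the myeloid list was higher in TOFA than in control effector cells, with a median of 0.487 and 8 of 10 members above 0. That median moved inside the random range under 4 of the 6 alternatives, at 0.115 and 0.234 with the floor at the 20th and 60th percentiles, 0.234 with the mean over probe sets and 0.0631 with the added constant. Mpeg1 stood at 155 against 7.47, and Cd14 and Fcer1g, chosen after their values were seen, at 74.4 against 19.9 and 59.1 against 13.8. These control signals lay under the floor of 43.4, and with the floor Cd14 and Fcer1g were under 2-fold apart. For Rap, the median of 0.716 over control may come from an unusual control array, which cannot be told apart from a Rap effect, and with 1 array per group a difference between single cultures stays open for TOFA.

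The hypothesis that TOFA effector cells lie toward the memory profile was examined over 10052 genes. It was taken to mean that the TOFA difference and the memory minus naive difference go together across genes. The rule, written after the values were seen, could argue against the hypothesis only with a low myeloid median for memory minus naive. With that median at 5.91, the comparison could favour the hypothesis or leave it open, but could not argue against it. Pearson's r was -0.0347 and Spearman's rho -0.0303, and genes are not independent replicates. RNA of other cells in the memory array, where the myeloid median was 5.91, could dilute r, so the hypothesis stays open. The T cell memory list had a median of -0.18 for TOFA minus control, with 7 of 22 members above 0. For memory minus naive its median was 1.11, with 14 of 22 above 0. The TOFA median moved inside the random range with the mean over probe sets. TOFA minus control and memory minus control had a covariance of 0.178 over 13831 genes against 0.0573 in simulated unchanged groups, but these differences share the control array. Their r was 0.28 over the 13831 genes and 0.31 over the 10052 genes. The simulated 0.50 follows from equal noise in all simulated groups, so setting r against it does not bear on the hypothesis. The simulated covariance was set by the probe set noise of TOFA against control (SD 0.34), not by that of memory against control (0.61). That noise leaves out differences of the control culture, so the covariance does not bear on the hypothesis either.

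A pair of control probe sets differed between arrays, chosen after their values were seen, with values as deposited. The probe set for the B1 repeat had a signal of 6656 in naive, 13003 in control effector, 5959.9 in Rap effector, 11794 in TOFA effector and 7106 in memory cells. The 3' probe set of pyruvate carboxylase had 80.6, 1007, 649, 329.5 and 139.6 in the same order.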
